A study of Mus musculus with 2 samples.

How the data were processed

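Total RNA sequencing of heart tissue from 14-day-old female B6CASTF1/J mice was analysed from the processed tables of 2 libraries. Per the labels, both were made from 300 ng of total RNA, with ERCC spike-in RNAs for libraries depleted of ribosomal RNA. The readme files deposited with the tables name the mouse assembly mm10 and the GENCODE annotation M21. The aligner, the quantification programs and their versions are not given in the sources used here. The column names of the gene tables and of 1 set of transcript tables are those that RSEM writes (called the first quantification), and those of the other transcript tables are those that kallisto writes (the second quantification). The animals carry 1 genome of CAST/EiJ descent while mm10 is of C57BL/6J, and how reads with CAST/EiJ alleles were handled is not given in the sources used here.

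Per the file headers, the gene and transcript tables of the first quantification hold the expected count of each feature, which the authors' program estimated by dividing reads between features and which was not normalized. The deposited TPM values are counts of transcripts scaled by effective length to the same sum in each library, over all rows, spike-ins included, and a posterior mean TPM with the bounds of its interval stands beside each, a score of precision for 1 library per the file headers. The transcript tables also hold, per the file headers, the percent of a gene's TPM in each transcript. The second quantification holds estimated counts and TPM per transcript, per the file headers, and its transcripts were summed per gene. Effective lengths were 99 bases below the transcript length in the first quantification and about 335 and 334 bases below it in the second in replicates 1 and 2, as seen in transcripts over 5000 bases. Gene names, types and positions came from GENCODE M21 by gene identifier.

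The gene table had 81881 rows: 55536 annotated genes, 96 spike-ins, 1 phiX sequence and 26248 rows with numeric identifiers. Only annotated genes were compared, spike-ins were described apart, and 86 genes had no row in the second quantification. Where a symbol occurred more than once in the annotation, the gene with the highest mean TPM was used. The libraries held 36404376 and 34569708 expected counts, of which 36197643 and 34358598 were in annotated genes. At this depth a count of 0 allows up to 3 counts, and intervals were set at 95%: Wilson intervals for shares, and exact Clopper-Pearson intervals for ratios of counts between the libraries, from the share of a gene's counts in replicate 1 scaled by the totals of annotated genes. Both cover counting error only, not the spread between animals.

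With 1 group of 2 libraries, no test between groups was possible, and values were given as mean ± SD over the 2. Agreement between the libraries was measured on log2(TPM + 1) over genes with a mean TPM of at least 1. The biological coefficient of variation was estimated with edgeR 4.0.16 under R 4.3.3 with no covariate, after TMM scaling (factors 0.982 and 1.02), and with DESeq2 1.42.0 as an alternative. Tested on simulated data for 13043 genes with true values of 0.05, 0.10 and 0.20, edgeR returned 0.0505, 0.0987 and 0.199, and the DESeq2 measure 0.0940, 0.122 and 0.206. Whether 1 library had been deposited as both was checked with the chi-square of the counts over genes with a mean expected count of at least 10.

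Genes were called different between the libraries by a rule of size: a difference of at least 1 in log2(TPM + 1), so at least 2-fold, after the median difference was removed, a mean expected count of at least 50, and deposited intervals that do not overlap. For each of 36 gene lists the median over members of the mean TPM, the SD of the 2 library medians and the number of members at 1 TPM or more were given, with the library medians or no SD where the median of means lay outside them. Differences of lists with at least 5 such members were set against 10000 random lists (seed 1) drawn from the same 20 bins of mean expression, and the percentile of the list's median is given. In simulated data 3.50% of 200 unshifted lists fell outside the central 95%, and a list shifted by -0.50 had percentile 0. Genes varied independently there, so this does not cover lists whose members vary together. Ratios were formed for 24 pairs of related genes, and transcript shares for sarcomere, calcium handling and intercalated disc genes with a mean TPM of at least 10. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

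The lists, pairs, rules, thresholds and most alternatives were chosen before the data were examined. Genes named in the text are the 4 members of each list with the highest mean TPM (all members of the Y chromosome list), the 20 genes with the highest mean TPM outside the mitochondrial genome, the 15 largest differences in each direction that met the rule of size, all members of the pairs, and the leading transcripts of at most 10 genes. Any other gene named was chosen after its values were seen. Some genes that this rule includes are not reported. The alternatives were a pseudocount of 0.1, no filter on low values, a mean TPM of at least 5, TPM rescaled without mitochondrial genes, spike-ins and the 10 most abundant genes, TMM-scaled counts, the second quantification, posterior mean TPM, other count minimums (200 for differing genes, 100 for the chi-square, 10 for spike-ins), no use of the intervals, protein-coding genes only, a detection limit of 0.1 TPM, counts with no correction for length, shares of TPM, and leaving out each replicate. Leaving out the airway secretory genes and keeping only list members with a mean TPM of at least 20 were added after the data were seen, as were 5 further gene lists used in the closing observations.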

Results

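Total RNA of heart tissue was sequenced from female B6CASTF1/J mice, first-generation hybrids of a C57BL/6J and a CAST/EiJ parent, at 14 days after birth. The series held 1 group of 2 libraries, each made from 300 ng of RNA with ERCC spike-in RNAs added, so the comparisons were descriptive: the levels of genes and transcripts in this tissue, and how far the 2 libraries differed. The sample labels gave the same donor for both libraries, and the description that both share could be read as a pool of 3 animals, while the tissue labels give each library a different animal number, so the spread given here as SD (n = 2) is that between the libraries and may hold a technical part. With 2 libraries in 1 group no groups could be compared and no test across samples was made; the smallest two-sided p that an exact sign test on 2 values can give is 0.5. Replicate 1 held 36404376 expected counts and replicate 2 held 34569708, and the intervals and limits from counts given below cover counting error only.

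Mitochondrial and contractile transcripts were prominent in both libraries. Of 55536 annotated genes, 12656 reached 1 TPM (a count of transcripts scaled to library and length) in both libraries, and 11510 of these were protein-coding. Nuclear protein-coding genes took 65.5% ± 0.713 (SD, n = 2) of the expected counts of genes, the mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 16.4% ± 0.556, and the 13 protein-coding genes of the mitochondrial genome 9.09% ± 0.428. Long noncoding RNAs took 3.22% ± 0.0705, small structured RNAs 2.91% ± 0.302 and pseudogenes 2.85% ± 0.102. A large part of the long noncoding share lay in a single gene annotated as such, Gm26917 (chromosome 17, 39843013 to 39846341). It held 611458 and 638712 expected counts in replicates 1 and 2. What RNA its reads came from was not tested. On the TPM scale, which divides by length, the share of the small structured RNAs was 19.2% ± 1.76 and that of nuclear protein-coding genes 43.4% ± 0.0316.

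Outside the mitochondrial genome the highest levels were those of Rn7s1 and Rn7s2, copies of the RNA of the signal recognition particle, at 70363 ± 6794 TPM each, and of Rn7sk, a regulator of transcription elongation (chromosome 9, 78175303 to 78175633, mm10), at 25275 ± 1674 TPM. Rn7s1 and Rn7s2 had identical values in each library. The pseudogenes Gm28661, Gm29216, Gm10925 and Gm28437, which lie side by side on chromosome 1, were also among the 20 highest, at 23659 ± 693, 11845 ± 1750, 10232 ± 1162 and 8102 ± 130 TPM. The levels of these short RNAs and pseudogenes differed between the quantifications: the second gave Rn7s1 and Rn7s2 at 1.05 and 0.291 TPM in replicates 1 and 2, Gm29216 at 2814 and 1049 TPM, and Gm10925 at 0.000227 and 0.00107 TPM. Gm28661 stayed high there, at 30327 and 30762 TPM. The expected counts of these pseudogenes were not whole numbers, so reads were divided between them and other features. Their levels, and the share of pseudogenes given above, depend on that division. The expected counts of the mitochondrial genes mt-Co1, mt-Co3 and mt-Atp6 were not all whole numbers either. The share of the protein-coding genes of the mitochondrial genome thus depends on such a division as well. Whether reads were divided between mitochondrial genes and these pseudogenes, or came from the pseudogenes themselves, was not tested. The highest messenger RNAs were those of the adult hemoglobins Hbb-bs (11514 ± 2070 TPM), Hba-a1 (9595 ± 1852) and Hba-a2 (9158 ± 1574), of the alpha myosin heavy chain Myh6 (10387 ± 129, chromosome 14, 54941921 to 54966927), and of Myl2, Actc1 and the oxygen-binding protein myoglobin, Mb (5390 ± 2.75).

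The lists of the sarcomere and of aerobic metabolism had higher medians than every list of another cell type. All 22 sarcomere genes had a mean TPM of at least 1, with medians of 729.6 and 732 TPM in replicates 1 and 2. Myl2, the ventricular regulatory light chain, was at 7231 ± 472 TPM, cardiac actin Actc1 at 6932 ± 391 and Myl3 at 4907 ± 272. Among the calcium handling genes (15 of 16 at 1 TPM or more, median over genes of the mean TPM 166 ± 7.92, the SD being that of the 2 library medians here and for the other lists) the calcium pump Atp2a2 was at 4121 ± 37.1 TPM and its inhibitor Pln at 2233 ± 8.29, ahead of Casq2 (451 ± 21.3) and Srl (429 ± 7.67). All 14 genes of the intercalated disc, the junction between cardiomyocytes, were detected (median 49.7 ± 4.04), with Ctnna1 at 242 ± 10.2 TPM and the connexin Gja1 at 226 ± 42.1. The list of ion channels and pacemaking had 17 of 19 members at 1 TPM or more and a median of 13.9 ± 0.636, with the potassium channel subunit Kcnip2 at 68.1 ± 7.93 TPM.

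The mitochondrially encoded proteins had the highest median of the 36 lists, 7185 ± 577 TPM, led by mt-Co1 at 31793 ± 1265. The nuclear genes of oxidative phosphorylation followed (23 of 23 detected, median 783 ± 1.73), with the ATP synthase subunit Atp5b at 3573 ± 115 TPM and the ADP/ATP carrier Slc25a4 at 2006 ± 27.5. Fatty acid oxidation (20 of 20, median 457 ± 6.50) was led by the fatty acid binding protein Fabp3 at 2421 ± 156 TPM, the tricarboxylic acid cycle (19 of 19, median 371 ± 0.438) included the malate dehydrogenase Mdh2 at 777 ± 15.2, and glycolysis (19 of 19, median 235 ± 4.42) was led by Gapdh at 1687 ± 62.7. The ribosomal proteins had a median of 235 ± 8.57 TPM (24 of 24) and the heat shock list one of 110 ± 4.26 (15 of 15), with the small chaperone Cryab at 572 ± 17.3.

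Both chamber programs were measured in these whole-heart libraries. The 8 ventricular genes had a median of 110 ± 38.0 TPM and the 12 atrial genes one of 17.9 ± 1.23. The atrial peptide Nppa was at 597 ± 124 TPM, the atrial light chain Myl7 at 338 ± 24.5, and the ventricular gene Lbh at 135 TPM in replicate 1 and 214 in replicate 2. Of 20 cardiac transcription factors 19 were detected (median 38.9 ± 2.32), led by Hopx at 223 ± 22.1 TPM. Igf2 (176 ± 21.4 TPM) and H19 (76.5 ± 14.0) were the highest of the 22 imprinted genes, of which 18 were detected (median 12.0 ± 0.0742). Proliferation genes were present at low levels: 24 of 25 cell cycle genes reached 1 TPM, with a median of 3.05 ± 0.651 and Pcna at 18.4 ± 2.21, and 17 of 18 replication-dependent histones did so, with a median over genes of the mean TPM of 17.4.

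Stromal and vascular lists were detected in full. The 18 fibroblast and matrix genes had a median of 94.0 ± 0.969 TPM (Sparc 576 ± 15.7, Col3a1 488 ± 15.9), the 17 endothelial genes 45.3 ± 0.955 (Fabp4 450 ± 54.4, Aqp1 160 ± 37.1), the 12 smooth muscle and pericyte genes 21.7 ± 0.400 (Acta2 169 ± 8.28) and the 10 epicardial genes 4.38 ± 1.16 (Msln 14.7 ± 0.318). Macrophage genes reached a median of 5.41 ± 2.28 TPM, 7.02 in replicate 1 and 3.79 in replicate 2, with 13 of 15 detected and Lyz2 at 32.4 ± 9.21. Blood cell genes, 11 of 13 detected, had a median of 14.9 ± 0.389. Fat was represented by 8 of 9 genes (median 10.9 ± 0.728), among them the brown fat uncoupling protein Ucp1 at 40.2 ± 10.7 TPM and Cidea at 36.2 ± 5.24. Lower medians were found for nerve and glia (0.820 and 0.960 in replicates 1 and 2, 7 of 13 detected) and for neutrophils and mast cells (1.21 over the mean TPM, 7 of 12).

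The lists of cartilage and valve, skeletal muscle, lung, and lymphocytes and thymus were close to the detection limit in the mean of the libraries. Cartilage and valve genes had 4 of 10 members at 1 TPM or more, with Fmod at 7.23 ± 0.0636 TPM. Skeletal muscle had 1 of 11 (Tnni2, 2.88 ± 0.573), lung 1 of 10 (Scgb1a1, described below) and lymphocytes and thymus 0 of 16. The interferon response was low, with 5 of 14 genes detected and a median of 0.555 ± 0.0566 TPM. Medians of the regulated lists were 34.7 ± 9.69 TPM for the glucocorticoid and fasting response (14 of 14 detected), 10.2 ± 0.962 for the circadian clock (16 of 16) and 5.87 and 4.81 in replicates 1 and 2 for immediate early genes (16 of 19). The abundant noncoding RNAs had a median of 66.4 ± 15.5 TPM (14 of 18), with the nuclear RNA Malat1, chosen after its values were seen, at 2429 ± 179.

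**Figure D1:**
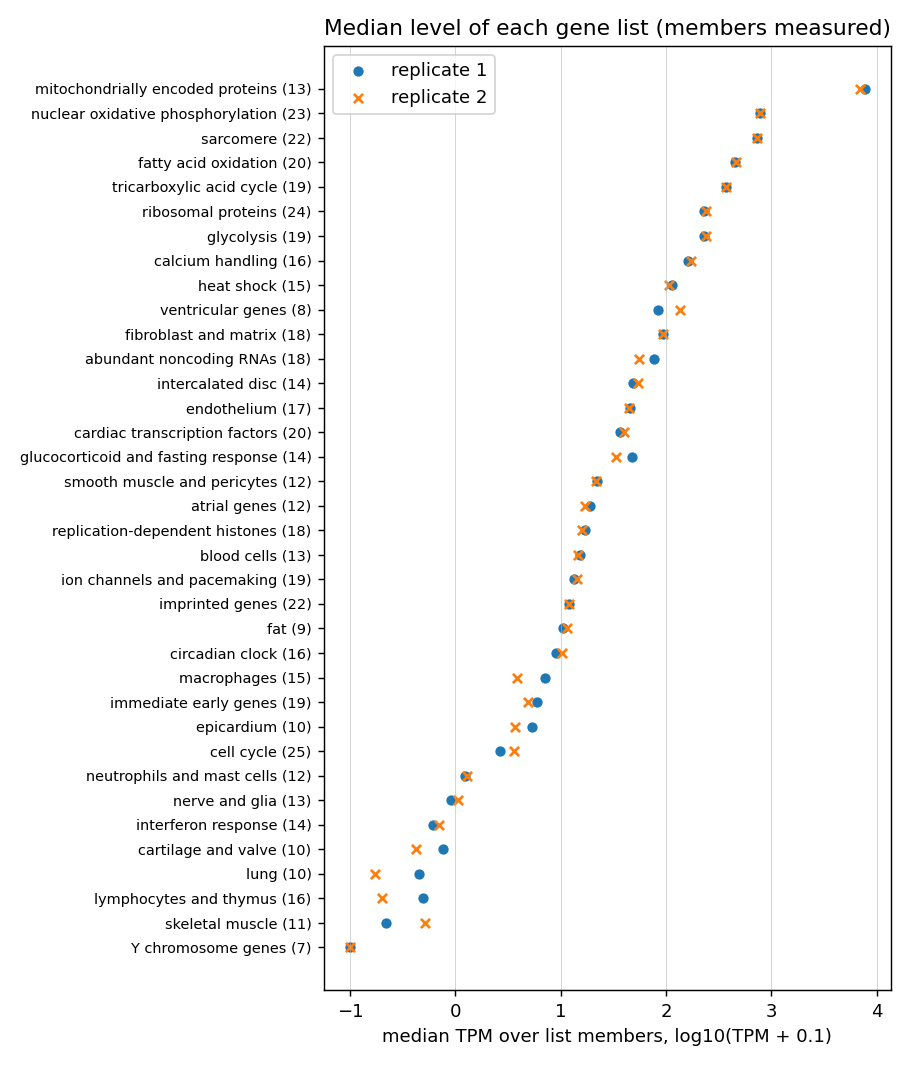
Median TPM over the measured members of each of 36 gene lists, on a log10 axis with 0.1 added, as circles for replicate 1 and crosses for replicate 2. The mitochondrially encoded proteins have the highest median (7185 ± 577 TPM) and the Y chromosome genes the lowest.

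The 7 genes of the Y chromosome list had almost no counts, as the label of female animals would have it: Ddx3y had 1 expected count in replicate 2, and Ddx3y in replicate 1 and Eif2s3y, Kdm5d, Uty, Zfy1, Zfy2 and Usp9y in both libraries had 0. A count of 0 allows up to 3 counts, or 0.0824 CPM (counts scaled to the depth of the library) in replicate 1 and 0.0868 in replicate 2. Xist, the RNA of the inactive X chromosome (chosen after its values were seen), was at 47.6 ± 1.64 TPM. The second quantification listed Uty at 1.03 TPM in replicate 1 and 0.541 in replicate 2.

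The heart members of 24 pairs of related genes were compared with the partner that marks another tissue, chamber or stage. The first gene was higher in both libraries in 22 pairs, and in the other 2 the partner had no counts. The alpha myosin heavy chain Myh6 exceeded the beta chain Myh7 (905 ± 14.5 TPM) by 11.5-fold, a log2 ratio of 3.52 ± 0.04 (SD, n = 2), so that Myh7 made up 8.01% ± 0.209 of their sum. The size of this ratio depended on the quantification and on the correction for length. The second quantification gave Myh7 more weight, at 2056 and 2021 TPM in replicates 1 and 2 beside 9317 and 9602 of Myh6. Expected counts of the first, with no correction for length, gave it less. Myh7 had 35772 and 35274 counts in replicates 1 and 2, beside 1065940 and 1033210 of Myh6. Cardiac troponin I, Tnni3, stood above the slow skeletal form Tnni1, which is typical of fetal heart, by a log2 ratio of 8.00 ± 0.87, with Tnni1 at 7.78 TPM in replicate 1 and 19.4 in replicate 2. Cardiac actin Actc1 exceeded skeletal actin Acta1 by 56.4-fold (log2 ratio 5.82 ± 0.02), and the embryonic hemoglobins Hba-x and Hbb-y had 0 counts beside 9595 ± 1852 TPM of Hba-a1 and 11514 ± 2070 TPM of Hbb-bs.

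Ventricular over atrial light chains gave log2 ratios of 4.42 ± 0.20 for Myl2/Myl7 and 4.15 ± 0.19 for Myl3/Myl4. Among the 22 pairs in which both genes had counts, the most unequal set a cardiac calcium gene against its skeletal muscle form: Ryr2 over Ryr1 reached 13.82 ± 0.76 and Atp2a2 over Atp2a1 13.32 ± 1.41, with Ryr1 at 6 and 17 expected counts and Atp2a1 at 19 and 70 in replicates 1 and 2. Casq2 exceeded Casq1 by 6.67 ± 0.02. For muscle against general forms of metabolic enzymes, the log2 ratios were 5.15 ± 0.25 for Ckm/Ckb, 5.06 ± 0.39 for Slc2a4/Slc2a1, 3.41 ± 0.14 for Eno3/Eno1, 2.97 ± 0.25 for Pgam2/Pgam1, 2.81 ± 0.0016 for Pfkm/Pfkl and 2.73 ± 0.05 for Cpt1b/Cpt1a. Ldhb exceeded Ldha by 1.42 ± 0.0041 and Hk2 exceeded Hk1 by 0.62 ± 0.22. Among the subunits of cytochrome oxidase, Cox6a2/Cox6a1 gave 2.05 ± 0.16, Cox8b/Cox8a 1.86 ± 0.07 and Cox7a1/Cox7a2 0.89 ± 0.03. The remaining pairs were Esrra/Esrrb (3.31 ± 0.38), Hcn2/Hcn4 (2.64 ± 0.36) and Fabp3/Fabp4 (2.43 ± 0.27). Only Cox7a1/Cox7a2 changed sign with the processing, to -0.0164 in the second quantification. Other ratios, Myh6/Myh7 among them, kept their sign but differed in size there, which the SD between the libraries does not cover.

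**Figure D2:**
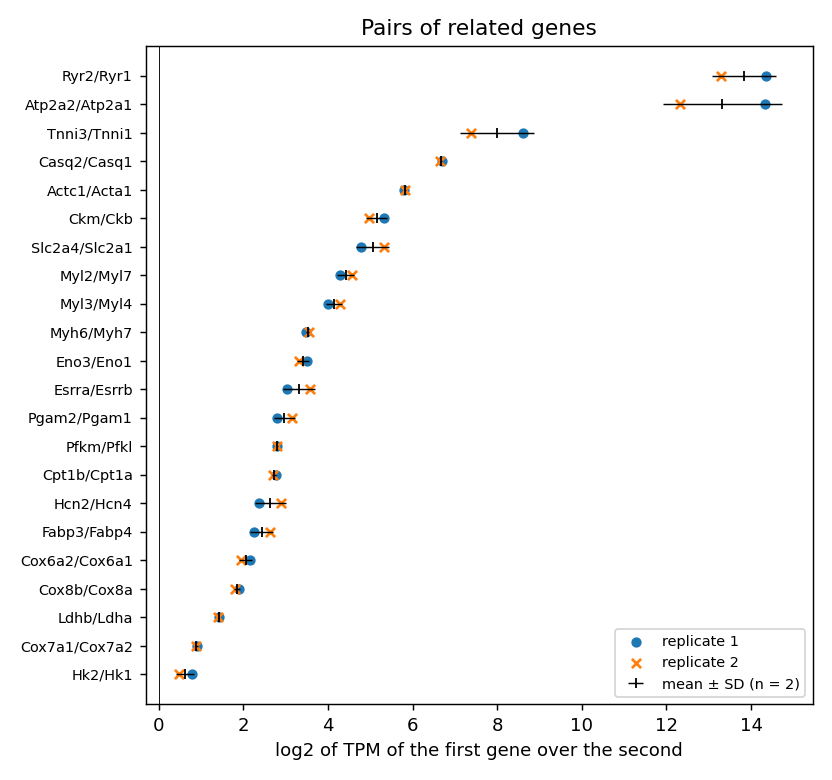
Log2 ratio of the TPM of the first gene to that of the second for the 22 pairs in which both had counts, as circles for replicate 1, crosses for replicate 2, and bars for the mean ± SD (n = 2). All ratios lie above 0, from 0.62 for Hk2/Hk1 to 13.82 for Ryr2/Ryr1.

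Most genes of the contractile, calcium handling and junction lists were read mainly from 1 transcript. Of 50 such genes with a mean TPM of at least 10, the leading transcript held at least 50% of the gene's TPM in 41 (36 by the second quantification), among them 4 genes with 1 annotated transcript only. For the other 46 genes these numbers were 37 and 32, and the leading transcript was the same in both libraries for all 46 (43 by the second quantification). In the first quantification Actc1-201 held nearly all of Actc1, Myl3-201 99.5% ± 0.0495 of Myl3, Tnnc1-202 99.3% ± 0.0707 of Tnnc1 and Tpm1-205 96.5% ± 0.226 of Tpm1, which encodes alpha tropomyosin. Atp2a2 was divided between Atp2a2-202 (74.5% ± 1.17) and Atp2a2-201 (23.8% ± 1.24), and Myh6 between Myh6-201 (41.7% ± 2.03) and Myh6-207 (27.7% ± 0.368). Myl2 was divided between Myl2-201 (57.6% ± 3.63) and the noncoding Myl2-210 (41.2% ± 3.54). The shares of Tnni3-201 (52.0% ± 1.57) and Tnni3-202, a transcript with a retained intron (46.2% ± 1.66), were close. Tnnt2-211 held 57.1% ± 2.47 of cardiac troponin T and Tnnt2-205 18.5% ± 0.467, and Pln-201 held 53.2% ± 0.665 of Pln and Pln-205 35.8% ± 1.06.

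The second quantification named the same leading transcript for 37 of these 46 genes. Shares could still differ by more than the SD between the libraries. It gave less to Myl3-201 (69.6%), Tpm1-205 (70.5%) and Myl2-201 (44.0%) and more to Myh6-201 (63.0%) and Atp2a2-202 (81.4%). Tnnc1-202 was little changed there (99.2%). The second quantification placed almost nothing on Tnnt2-211, giving 49.3% to Tnnt2-209 in its place, and it led with Tnni3-204 (47.1%) and Pln-204 (59.1%). For Tnnt2 and Pln, then, the leading isoform differed between the quantifications, while for Tnni3 the second quantification had different leaders in the 2 libraries and Tnni3-201 close behind in the mean (45.7%).

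Most genes had similar levels in the 2 libraries. Over the 13043 genes with a mean TPM of at least 1, log2(TPM + 1) correlated across genes with Pearson's r = 0.985 and Spearman's rho = 0.982, where genes are not independent replicates. The SD of the differences was 0.307. After the median difference was removed, 81.3% of these genes lay within 1.2-fold between the libraries in TPM + 1. On that scale 137 were at least 2-fold apart. The added 1 makes genes of low TPM appear closer than their TPM values are. The biological coefficient of variation between the libraries was 0.102 by edgeR and 0.181 by the DESeq2 measure. The chi-square of the counts was 12.6 per degree of freedom over genes with a mean expected count of at least 10, well beyond sampling noise, so the values were not those of 1 library deposited as both.

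A gene was called different between the libraries when its TPM + 1 differed at least 2-fold after the median difference was removed. Its mean expected count also had to be at least 50, and the deposited intervals of its TPM could not overlap. Genes of low TPM can miss this rule although their TPM values differ more than 2-fold. Of 12280 genes with enough counts, 45 met this rule, 39 of them higher in replicate 1 and 6 higher in replicate 2. Secretory genes of the airway epithelium differed most. Scgb1a1, the club cell secretory protein (chromosome 19, 9083636 to 9087958), was at 97.6 TPM in replicate 1 and 5.96 in replicate 2, with 1034 and 61 expected counts, a ratio of 16.1 in CPM (95% exact counting interval 12.4 to 21.2). Scgb3a2 had 525 and 29 expected counts (ratio 17.2, 11.8 to 25.9), Scgb3a1 273 and 8 (32.4, 16.2 to 75.8), Cyp2f2 499 and 36 (13.2), Bpifa1 99 and 4 (23.5, 8.89 to 87.9) and Wfdc2 103 and 13 (7.52, 4.21 to 14.6).

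Members of the glucocorticoid and fasting list formed another part of the set. Of the 14 genes of the glucocorticoid and fasting list, 4 were higher in replicate 1 by this rule and 1 higher in replicate 2. The metallothioneins Mt1 and Mt2, neighbours on chromosome 8 (94179082 to 94180327 and 94172664 to 94173568), were at 168 against 58.7 TPM and 29.7 against 5.65 TPM. The cell cycle inhibitor Cdkn1a was at 43.9 and 11.8 TPM, a ratio of 3.95 in CPM (3.59 to 4.35), and Fkbp5, a cochaperone of the glucocorticoid receptor, at 15.5 and 4.53 TPM (3.27, 2.90 to 3.70). The clock genes Per1 (41.9 and 14.5 TPM) and Per2 (7.91 and 1.91 TPM) were the 2 of 16 circadian genes that met the rule, both higher in replicate 1. Xdh (27.6 and 8.04 TPM), the acute phase protein Hp (21.7 and 6.51), Fam107a (6.29 and 1.29), Slc10a6 (4.32 and 0.780) and the chemokine Cxcl13 (4.16 and 0.670) were also among the genes with the largest differences toward replicate 1.

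The 6 genes higher in replicate 2 were the transcription factor Sox4 (13.1 and 29.9 TPM in replicates 1 and 2, a ratio of 2.33 in CPM, 2.20 to 2.47), Angptl4, an inhibitor of lipoprotein lipase (8.56 and 20.5 TPM), Tnni1 (7.78 and 19.4), H3f3c, annotated as a processed pseudogene (8.98 and 24.4), Prnd (1.33 and 5.11) and the unnamed gene AC124502.3 (0.410 and 2.29). In the second quantification 3 of these 6 were less than 2-fold apart: H3f3c was at 0 TPM in both libraries, Prnd at 0.926 and 1.61 and AC124502.3 at 1.62 and 2.25. Of all 45 genes, 35 met the rule there, applied without the condition on intervals. With a pseudocount of 0.1 the number of genes meeting the rule was 79, in which all 45 were included. On simulated counts for 13043 genes, the rule recovered 93% of 100 genes changed 3-fold and 100% of 100 changed 6-fold, and it called 0 of 12843 unchanged genes. That simulation gave every gene the same coefficient of variation, 0.102, and intervals from counting error only. It therefore cannot show how many false calls arise where single genes vary more or where reads are assigned wrongly.

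**Figure D3:**
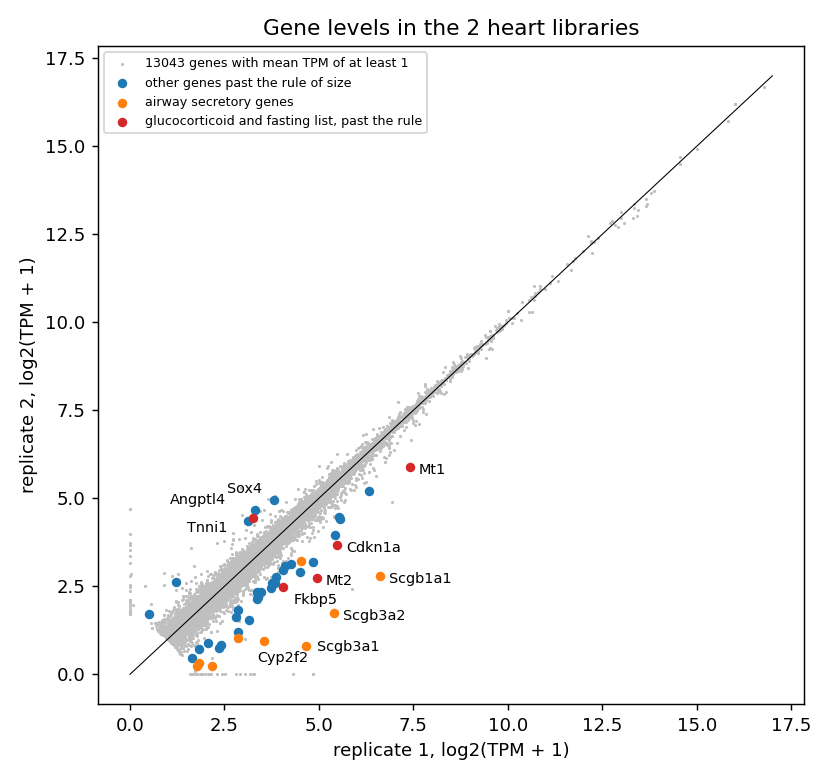
Log2(TPM + 1) of the 13043 genes with a mean TPM of at least 1 in replicate 1 (x axis) against replicate 2 (y axis), with the line of equality. Coloured points are the 45 genes that met the rule, in orange the airway secretory genes and in red the members of the glucocorticoid and fasting list, and 39 of the 45 lie on the side of replicate 1.

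Gene lists fixed beforehand moved between the libraries in the same 2 directions. The median difference of 12 of 31 lists lay outside the central 95% of random lists matched for expression, where 1.55 would be so if genes varied independently. Members of a list can vary together and some lists share genes, so 1.55 is too low a yardstick for such lists. Differences are given as replicate 2 minus replicate 1 in log2(TPM + 1). The glucocorticoid and fasting response had a median of -0.69 (percentile 0, 10 of 14 members higher in replicate 1) and the immediate early genes one of -0.42 (percentile 0, 15 of 16 members), with Klf2, a flow-responsive factor of the endothelium, at 47.1 and 33.2 TPM and Jun at 30.4 and 21.3. Blood cell genes (-0.35, percentile 0, 8 of 11 members) included Hbb-bs at 12978 and 10050 TPM. Macrophage genes (-0.35, percentile 0, 9 of 13 members) included the lysozyme Lyz2 at 38.9 and 25.9 TPM and the complement gene C1qb at 17.4 and 12.7.

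Smaller shifts toward replicate 1 were those of the mitochondrially encoded proteins (-0.15, percentile 0, 12 of 13 members), atrial genes (-0.10, percentile 0.43, 9 of 12), endothelium (-0.09, percentile 0.13, 13 of 17), abundant noncoding RNAs (-0.08, percentile 0.28, 8 of 14) and replication-dependent histones (-0.07, percentile 2.39, 11 of 17). The lists shifted toward replicate 2 were ventricular genes (0.15, percentile 98.2, 7 of 8 members), cell cycle genes (0.12, percentile 97.6, 16 of 24) and the intercalated disc (0.12, percentile 98.6, 12 of 14). Nppa was at 685 TPM in replicate 1 and 509 in replicate 2, and Gja1 at 196 and 256. The lists of sarcomere, calcium handling, fatty acid oxidation, glycolysis, tricarboxylic acid cycle and nuclear oxidative phosphorylation genes stayed inside the range of random lists, with medians from -0.01 for calcium handling to 0.04 for fatty acid oxidation.

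The blood cell call ended when the most abundant genes, which include Hbb-bs, Hba-a1 and Hba-a2, were removed before scaling (median -0.09, percentile 12.3), and the histone median changed sign in the second quantification (0.0015). The atrial call ended in the second quantification (-0.04, percentile 2.93), and the cell cycle call with TMM-scaled counts (0.08, percentile 93.8) and in the second quantification (0.15, percentile 96.5). The ventricular call ended at a mean TPM of 5 (0.13, percentile 97.0) and in the second quantification (0.17, percentile 96.2), and the histone call with every scaling tried. The intercalated disc call ended only when members at 20 TPM or more were kept (0.10, percentile 94.7), a setting chosen after the data were seen. The 5 lists with fewer than 5 members at 1 TPM had no percentile. Among them, the summed counts of lymphocyte and thymus genes were 350 in replicate 1 and 152 in replicate 2, a ratio of 2.19 in CPM (1.80 to 2.66), those of lung genes 1177 and 114 (9.80, 8.08 to 12.0; 143 and 53 without Scgb1a1, 2.56, 1.86 to 3.58, a setting chosen after the data were seen), and those of skeletal muscle genes 118 and 291 (0.385, 0.308 to 0.478).

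**Figure D4:**
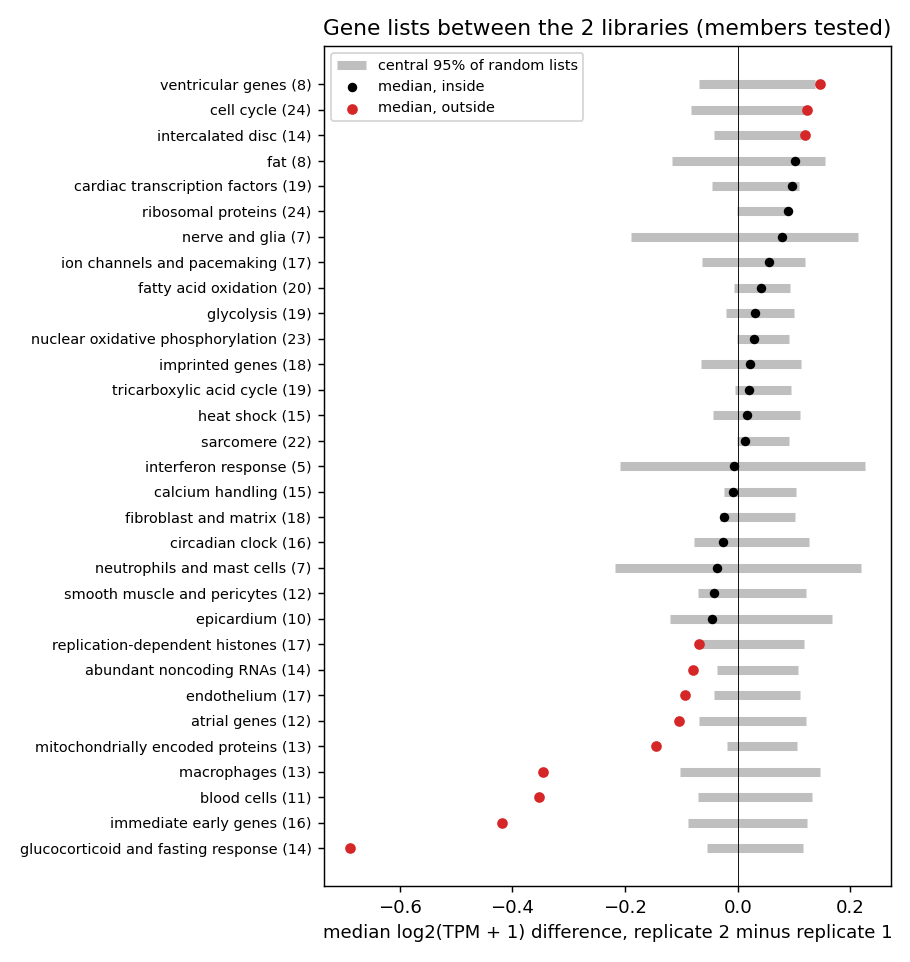
Median difference of each gene list between the libraries (x axis, log2(TPM + 1), replicate 2 minus replicate 1), with the central 95% of 10000 random lists matched for expression as grey bars. Red points are the 12 lists outside their bar, from -0.69 for the glucocorticoid and fasting response to 0.15 for the ventricular genes.

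Short structured RNAs separated the 2 deposited quantifications. Rn7sk was at 25275 ± 1674 TPM in the first and at 1.37 and 0 TPM in the second in replicates 1 and 2, and Rpph1, the RNA of ribonuclease P, was at 5030 ± 772 TPM in the first and at 0.963 and 1.60 in the second. The mitochondrial genes mt-Atp8 and mt-Nd4l, at means of 3088 and 7185 TPM in the first quantification, were at 0 and 98.2 TPM in the second (mt-Atp8 and mt-Nd4l were chosen after their values were seen). Over 13037 genes the log2(TPM + 1) values of the 2 quantifications correlated across genes with Pearson's r = 0.867 in replicate 1 and 0.863 in replicate 2, and with Spearman's rho = 0.902 and 0.900. Myh6 (9317 and 9602 TPM in the second) and Mb (6824 and 7001) were among the genes kept at a high level by both.

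**Figure D5:**
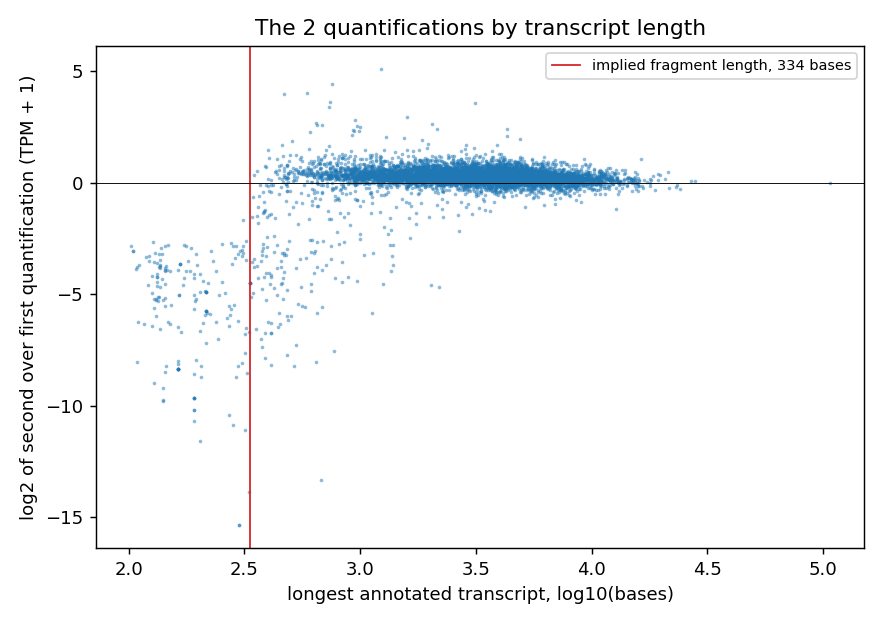
Log2 ratio of the second to the first quantification (mean TPM + 1, y axis) against the length of the longest annotated transcript (log10 of bases, x axis) for genes with a mean TPM of at least 5 in the first. The vertical line marks the fragment length of 334 bases implied by the second, to the left of which nearly all genes lie far below 0.

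The spike-in RNAs took a slightly higher share of replicate 2 than of replicate 1. They took 0.568% of the expected counts of replicate 1 (95% Wilson interval 0.565 to 0.570) and 0.611% of those of replicate 2 (0.608 to 0.613), a mean of 0.589% ± 0.0303. Of 96 spike-in sequences, 66 had counts in replicate 1 and 69 in replicate 2, and 44 in each had an expected count of at least 10. Over the 43 with at least 10 counts in both, log2(TPM + 1) correlated with r = 0.999 across sequences, and the SD of the differences was 0.143. The SD of 0.307 of the genes was taken with no minimum count, so the 2 values are not directly comparable.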

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

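The tests of alveolar markers, read assignment, normalization, clock genes and transcript length were chosen only after the result was seen. The rows with numeric identifiers, which no comparison used, held 4 expected counts in replicate 1 and 3.92 in replicate 2, just above the 3 that a count of 0 allows.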

How the results depend on the processing

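The setting with list members at 20 TPM or more and the one without airway genes were chosen after the data were seen; the others were fixed earlier. The correlation between libraries (0.985) was 0.970 with a pseudocount of 0.1, 0.992 with no filter, 0.984 at a mean TPM of 5, 0.981 with rescaled TPM, 0.992 with TMM-scaled counts, 0.987 in the second quantification, 0.992 with posterior mean TPM and 0.990 for protein-coding genes. The coefficient of variation of 0.102 was 0.181 with DESeq2, where simulated values of 0.10 and 0.20 returned 0.122 and 0.206; the cause of the difference was not tested. The 45 differing genes became 79 with a pseudocount of 0.1, as a smaller one enlarges differences of low values; they numbered 30 to 63 under the other settings and 36 without airway genes. The 12 shifted lists were 9 to 14 under the planned settings and 6 at a mean TPM of 20, where fewer genes and lists are tested. The histone median of -0.07 reversed to 0.0015 in the second quantification and 0.0432 at a mean TPM of 20, and the Cox7a1/Cox7a2 ratio to -0.0164 in the second quantification; the cause was not tested. The correlation between quantifications was 0.783 and 0.777 (replicates 1 and 2) with a pseudocount of 0.1 and 0.777 and 0.769 at a mean TPM of 5. In replicate 2, 44 of 69 spike-ins had 10 counts or more. By TPM the protein-coding share was 43.4%, since short RNAs weigh more. Without replicate 1 or 2, detected list genes numbered 458 and 462, leading pair members 22 and 22, transcript shares of 50% or more 40 and 41, spike-in shares 0.611% and 0.568%, and protein-coding shares 66.0% and 65.0%.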

Other observations

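The tests of alveolar markers, read assignment, normalization, clock genes and transcript length, and the members named from the added gene lists, were chosen after the result was seen. Rag1, the recombinase of immature lymphocytes, was chosen after its values were seen. It had 82 expected counts in replicate 1 and 1 in replicate 2, a ratio of 77.8 in CPM (95% exact counting interval 13.6 to 3111). The B cell genes Cd79a (24 and 17 counts) and Cd79b (23 and 25) had ratios of 1.34 (0.690 to 2.66) and 0.873 (0.474 to 1.60), whose intervals include equality. Of the skeletal muscle genes Atp2a1 had 19 and 70 counts, whereas Tnni2, the highest of them, had 59 and 43. The natriuretic peptide Nppb, also chosen after its values were seen, was at 31.1 TPM in replicate 1 and 59.8 in replicate 2, opposite to Nppa at 685 and 509.

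Airway secretory transcripts held the largest differences in log2(TPM + 1) among the genes that met the rule of size, though not every one of them ranked at the top. All 9 genes of a list drawn up from them were higher in replicate 1, with summed counts of 3383 and 348. Their assignment by the first quantification is argued against, since the second gave a median ratio of 11.6 over the 9 genes, with single genes from 2.94 to 41.7. Alveolar lung tissue as the main source is argued against, since 6 alveolar markers together reached 7.06% of the count of Scgb1a1 in replicate 1 (upper limit 8.88%). Their summed counts of 73 and 27 were still higher in replicate 1 (ratio 2.57, 1.63 to 4.15), with Sftpa1 at 43 and 2, Sftpb at 14 and 1, Sftpd at 12 and 0 and, the other way, Sftpc at 0 and 16. A hypothesis that stays open is that a piece of conducting airway was carried over with the heart: 18 markers of ciliated airway cells, none of them at 1 TPM or more in the mean, had 219 and 58 counts, a ratio of 3.58 (2.67 to 4.87), which was 2.36 (1.72 to 3.27) without Dnah5, at 80 and 2 counts, and 1.95 (1.40 to 2.74) without Dnah5 and Dnah9, both left out after their counts were seen, while Rsph1 went the other way at 21 and 25. These counts cannot tell tissue carried over from any other way in which airway RNA or its reads could enter the library. Such other ways were not tested.

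Genes that respond to glucocorticoids were higher in replicate 1. A scaling common to all genes is argued against, since it would move the random lists alongside the fixed list, which had percentile 0. The median of the fixed list was -0.62 or lower under the rescaled, TMM-scaled and second-quantification values. TMM scaling could move it little, with factors of 0.982 and 1.02 in replicates 1 and 2. Stronger glucocorticoid exposure of the tissue of replicate 1 may account for the pattern: a further list of 17 induced genes had a median of -0.49, percentile 0 among random lists, with 16 of 17 higher in replicate 1, whereas 4 of the 14 members of the fixed list went the other way, Pdk4 (246 and 265 TPM), Txnip (231 and 273), Angptl4 (8.56 and 20.5) and Ucp3 (20.9 and 37.6). A different time of day stays open too, since the 14 clock genes other than Per1 and Per2 had a median absolute difference of 0.16 (percentile 80.5), which decides nothing under bounds of which the lower was reset after this value was seen, and Nr1d1 was at 8.67 and 17.8 TPM (Ucp3 and Nr1d1 were chosen after their values were seen). Handling, feeding and the make-up of the libraries, which the labels leave unclear, were not tested.

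The loss of short RNAs from the second quantification followed length. Of 178 genes with transcripts shorter than the implied fragment length and a mean TPM of at least 5, 174 were under 1 TPM there, against 49 of 8428 genes longer than 500 bases, a difference of 97.2 percentage points. Sharing of reads between copies is argued against as the whole cause, since 48 of 49 short genes with whole expected counts in both libraries (98.0%, 95% exact interval 89.1 to 99.9) were lost as well. The values are consistent with a fragment length set above the length of these RNAs, a hypothesis that bears on 19.4% and 21.8% of the TPM of the first quantification in replicates 1 and 2. The settings of the authors' program were not seen.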
